A study of Drosophila melanogaster with 4 samples.

How the data were processed

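Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark written by Polycomb repressive complex PRC2, was profiled by chromatin immunoprecipitation and sequencing in whole embryos of the wild-type Drosophila melanogaster strain Oregon-R, collected at 14 to 16 h of development. The series holds 4 samples, of which 2 are ChIP libraries and 2 are the matching inputs, numbered 1 and 2 in the titles. Cross-linked chromatin was precipitated on protein A beads with an antibody to H3K27me3, per the labels' protocols. Each input is named in the labels as the input for the region list of the ChIP library with the same number.

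The files analysed here are 3 lists of enriched regions, one per ChIP library and one for the series as a whole. The list of the whole series is called the series list below. How it was made from the replicates is not given in the sources used here. Each row holds a sequence name, a start, an end and one score, per the file headers in 1-based GFF3 form. The score in the deposited files is a positive number per region, and its scale, its caller and the threshold behind the lists are not given in the sources used here. Bowtie 0.12.7, a short-read aligner, is named in the submitters' processing notes. No read counts were used, so the sequencing depth of each library is unknown and no interval that needs it is given. A region missing from a list is only one that did not pass the authors' threshold, which can also happen where reads cannot be placed. The inputs were not analysed here on their own, because the lists already hold the authors' comparison of ChIP with input.

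The genome build is not named in the sources used here. The 14 sequence names and lengths in the file headers are those of Release 5 of the fly genome, and all coordinates below are in that build. The gene table at hand belongs to Release 6 and was used neither for coordinates nor for names. The analyses of gene 5′ ends and of fixed gene lists, planned for the case that the builds matched, were therefore not run, and regions are named by position alone. The 6 major arms are 2L, 2R, 3L, 3R, X and 4. The 8 other sequences are heterochromatic or unplaced scaffolds. In the series list, 1 region ran past the end of its arm and was clipped to it.

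Overlap between replicates was counted from 1 bp upwards. Chance overlap came from 10000 circular shifts of the replicate 1 regions along each sequence, which keep region widths and spacing, with one-sided permutation p-values whose smallest possible value is 1e-04. The 3 overlap measures formed one family with Benjamini-Hochberg adjustment. Unplaceable sequence was not masked in the shifts. Shares of regions carry 95% Wilson intervals, which cover counting error only. Scores were used to rank or filter regions within a list, and their correlation was taken across regions that overlap one to one, with a 95% interval from 2000 bootstrap draws. Regions are not independent replicates, so these values describe the lists. The replicate label alone says that the libraries are separate samples; whether they came from separate embryo collections is not given in the sources used here. With 2 values in each of 2 groups no 2-sided exact permutation test can go below p = 0.333.

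Named regions followed a rule set before the data were examined, namely the 10 longest stretches called in both replicates, the 5 highest-scoring regions of each replicate and the 5 longest regions found in one replicate alone. Regions of at least 10 kb are called broad and regions under 2 kb narrow. These terms and the width classes were chosen after the widths were seen. Alternatives covered a minimum overlap of 50% of the shorter or of both regions, the regions at or above the median score of each list, merging of regions under 1 kb apart, the major arms alone and a minimum width of 1 kb. Those added after the data were seen were a minimum width of 5 kb, shifts of 100 kb to 1 Mb, the major arms for counts of regions, and the narrowest replicate width applied to the series list.

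Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The overlap code was tested on simulated data. It recovered the overlap of 3 of 3 simulated lists exactly. Of 91 breaks of replicate 1, 31 left in place were all found, and of 100 sets of breaks placed at random 3 had p under 0.05. Of 100 simulated lists with no shared placement, 5 had p under 0.05 for the share of replicate 1 regions and 4 for shared sequence. The random lists and breaks were made with the same moves that the tests use. They check the code, and not whether such moves suit real lists.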

Results

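H3K27me3-enriched regions were mapped in 14 to 16 h Oregon-R embryos in 2 ChIP replicates, each called against its own input. Replicate 1 held 1486 regions that covered 14.4 Mb, and replicate 2 held 1459 regions that covered 14.9 Mb. On the 6 major arms, 120 Mb in all, these regions took up 11.9% of the sequence in replicate 1 and 12.3% in replicate 2. The series list held 2279 regions and 17.8 Mb, or 14.7% of the major arms. Off the major arms there were 16 regions in replicate 1 and 17 in replicate 2. The read depth behind the calls is unknown.

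The first question was how the mark is laid out along the genome. Most of the called sequence lay in a minority of broad domains. Regions of at least 10 kb numbered 300 in replicate 1 and 311 in replicate 2, 20.2% and 21.3% of all regions, and held 76.4% and 77.2% of the called bases. Those of at least 50 kb numbered 61 and 63 and held 39.2% and 39.4%. The longest spanned 205 kb in replicate 1 and 208 kb in replicate 2. At the other end, 544 regions of replicate 1 and 520 of replicate 2 were narrower than 2 kb and together held 5.99% and 5.55% of the called bases. Median widths were 2569 bp and 2717 bp, and the narrowest region was 1301 bp in both lists.

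Broad regions also had the higher scores, which are the authors' own value for each region. The median score was 1.57 for regions of at least 10 kb against 0.572 for the others in replicate 1, and 1.54 against 0.554 in replicate 2. Across regions, width and score had a Spearman correlation of 0.80 in replicate 1 and 0.83 in replicate 2, and of 0.56 in the series list. Some regions under 3 kb fell outside this trend with scores above 2. In replicate 1 they were 6, of which 4 lay on 2R between 2224849 and 2306580, and in replicate 2 they were 8, of which 5 lay on 2R between 2224787 and 2307509. This stretch of 2R was picked out after the scores were seen. Another region under 3 kb lay elsewhere on 2R, at 3901506 to 3904128 in replicate 1 (score 2.34) and 3901512 to 3904108 in replicate 2 (2.28). It ended just before a 35.5 kb region with a higher score, which began at 3904222 and 3904260. It may thus be part of a broad domain and not a separate narrow site.

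**Figure D1:**
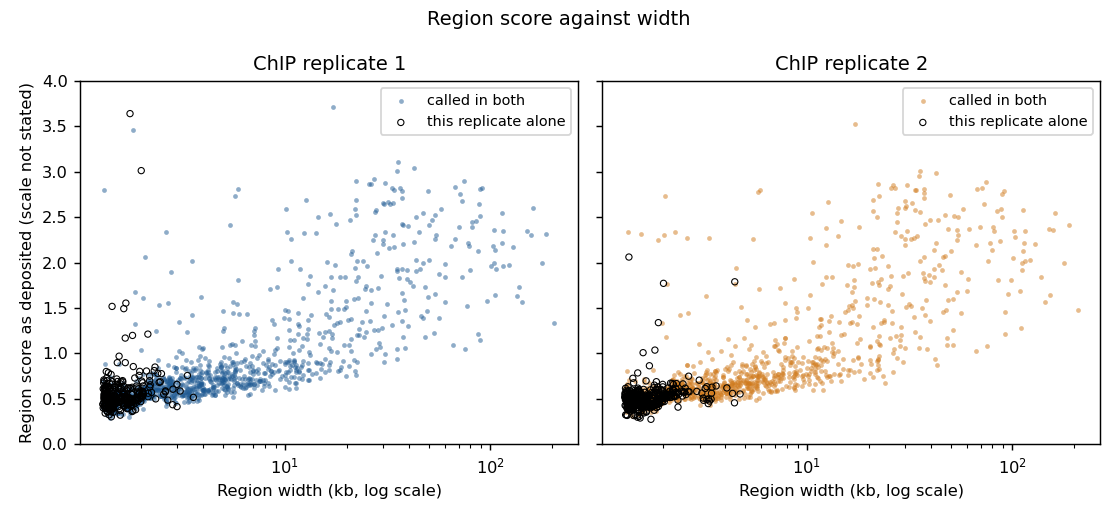
Score of each region as deposited against its width in kb on a log axis, for ChIP replicate 1 (left) and ChIP replicate 2 (right). Filled points are regions that overlap the other replicate by at least 1 bp, and open points are regions of that replicate alone, which crowd at widths under 5 kb and mostly at scores under 1.

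The 10 longest stretches called in both replicates lay on 2L (3), X (3), 3L (2) and 3R (2), and summed to 1.58 Mb, 11.6% of the shared bases. The longest covered 205 kb of 3L from 18244516 to 18449376, with a score of 1.34 in replicate 1 and 1.48 in replicate 2. Next came 186 kb of 3R from 12624865 to 12810710, with scores of 2.31 and 2.42, and 178 kb of 2L from 11316994 to 11495123, with scores of 2.00 and 1.99. The fourth, on 3L from 12565573 to 12725962, spanned 160 kb and had the highest scores of the 10, 2.60 and 2.55. On X the stretches ran from 4266788 to 4424575 (158 kb), from 7415489 to 7550935 (135 kb) and from 20503040 to 20631325 (128 kb). The other 2 on 2L ran from 5366350 to 5517059 (151 kb) and from 15303781 to 15446874 (143 kb). On 3R the remaining stretch ran from 2738213 to 2875472 (137 kb). Each of the 10 lay within 1 region of the series list.

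**Figure D2:**
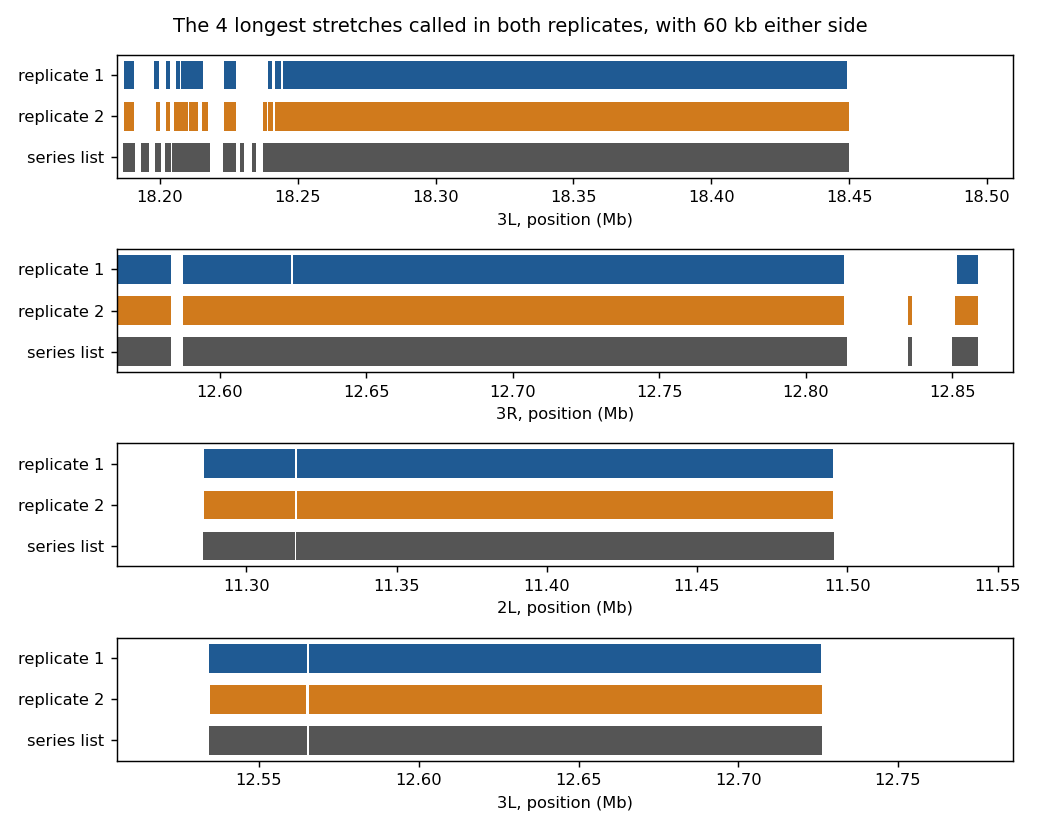
Maps of the 4 longest stretches called in both replicates, drawn to scale with 60 kb either side. Bars are called regions of replicate 1, replicate 2 and the series list against position in Mb, and the ends of the long regions lie close together in all 3 tracks except at the left end of the 3L stretch near 18.2 Mb, where they fall at different places; the shortest breaks are too narrow to show.

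By score, the leading region in both replicates was a compact one on 2R. It ran from 5859754 to 5876864 (17.1 kb) with a score of 3.72 in replicate 1, and from 5859778 to 5876834 with a score of 3.52 in replicate 2. A 35.5 kb region of 2R had scores of 3.10 (3904222 to 3939717 in replicate 1) and 3.01 (3904260 to 3939775 in replicate 2). A 42.4 kb region of X had scores of 3.04 (17645684 to 17688078) and 2.99 (17645666 to 17688087). The top 5 of replicate 2 were completed by regions of 35.2 kb on 2R (19505154 to 19540346, score 2.95) and of 74.3 kb on 3R (17233833 to 17308136, score 2.89). In replicate 1, ranks 2 and 3, above the 35.5 kb and 42.4 kb regions, belonged to narrow 2R regions. They lay at 2257120 to 2258881 (3.64) and 2259528 to 2261346 (3.46), of which the first was not called in replicate 2.

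Called sequence was spread unevenly over the arms. It took up 13.5% ± 0.38 (SD, n = 2) of 2L, 13.3% ± 0.50 (SD, n = 2) of 3L and 12.8% ± 0.24 (SD, n = 2) of 3R. The shares were lower on X, at 10.2% ± 0.24 (SD, n = 2), and on 2R, at 10.1% ± 0.15 (SD, n = 2). The small chromosome 4 had the largest share, 16.2% ± 0.023 (SD, n = 2), from 13 regions in replicate 1 and 12 in replicate 2, 8 of them broad in each. The gap between X or 2R and the other large arms exceeded the spread between replicates, and with 2 values per arm it was not tested. In regions per Mb, 3L was densest with 15.5 and 15.1 in the replicates, and X was sparsest among the 5 large arms with 9.32 and 8.83. The heterochromatic and unplaced scaffolds had at most 0.782% of their length called in either replicate, and the largest of them, Uextra, had no region in any list. All these shares are of full sequence length, and how much of it reads can be placed on was not examined. A lack of calls is therefore no evidence that the mark is absent.

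Within arms the share called varied from window to window. Among 120 windows of 1 Mb (arm ends under 500 kb left out), the median share called was 10.4%, 4 windows exceeded 30% in both replicates and 3 had no region in either. Placement of reads was not examined here either, so windows without a call need not lack the mark. The 4 windows held 10.6% of the called bases of the major arms. The densest window was 3R from 12 to 13 Mb, with 46.2% ± 0.77 (SD, n = 2), followed by X from 7 to 8 Mb with 39.1% ± 2.1 (SD, n = 2) and 3R from 2 to 3 Mb with 38.1% ± 0.15 (SD, n = 2). The last 147 kb of 2R were called over 76.3% of their length in replicate 1 and 77.5% in replicate 2. Among the windows with a call, the lowest shares were on X, at 0.0899% ± 0.13 (SD, n = 2) from 11 to 12 Mb and 0.135% ± 0.0019 (SD, n = 2) from 6 to 7 Mb.

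**Figure D3:**
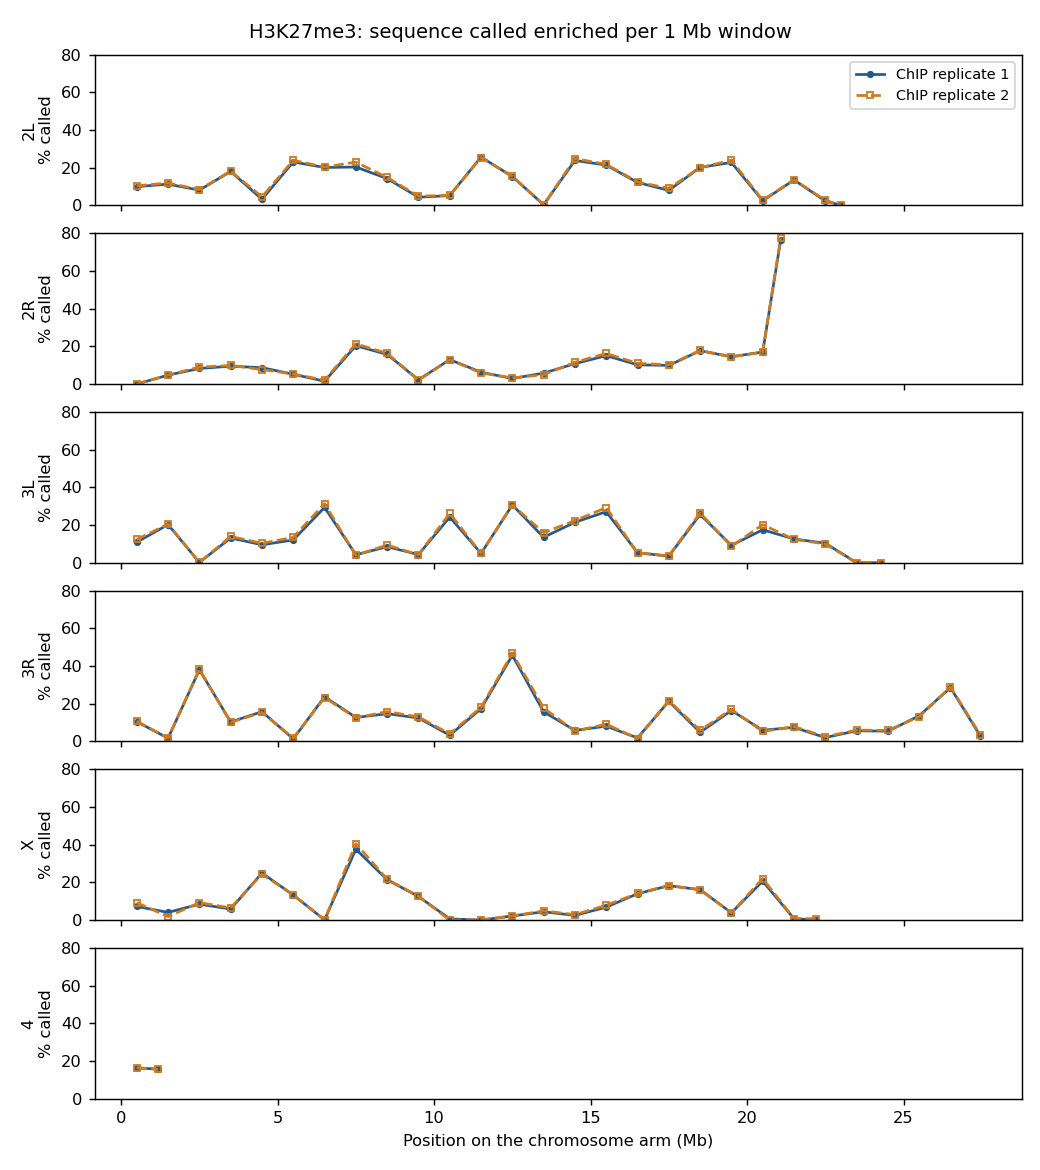
Percent of each 1 Mb window called enriched along the 6 major arms, with ChIP replicate 1 as filled circles and ChIP replicate 2 as open squares; the last window of an arm is shorter than 1 Mb. The lines of the replicates differ by at most 3.00 percentage points in any of the 120 windows of at least 500 kb, and the highest full window is 3R from 12 to 13 Mb.

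The second comparison asked how far the replicates called the same regions. Every region of at least 5 kb in one replicate overlapped a region of the other, 466 of replicate 1 and 491 of replicate 2, and the differences lay among the short ones. In all, 1208 of the 1486 regions of replicate 1, or 81.3% (Wilson interval 79.2 to 83.2), overlapped replicate 2. In the other direction it was 1101 of 1459, or 75.5% (73.2 to 77.6). Circular shifts gave a median of 16.96% and 16.93%, with a highest value of 39.6% and 39.1% (one-sided permutation p = 1e-04, the smallest possible, and adjusted p = 1e-04 for both). In bases, 13.6 Mb were called in both replicates and 15.7 Mb in either, a shared fraction of 86.4%, against a median of 6.41% and a highest of 22.2% under shifts (one-sided permutation p = 1e-04, adjusted p = 1e-04). Replicate 2 contained 94.4% of the replicate 1 bases, and replicate 1 contained 91.1% of the replicate 2 bases.

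Overlap depended on width. Of regions of 2 to 5 kb, 92.2% (89.5 to 94.3) of replicate 1 and 84.6% (81.0 to 87.6) of replicate 2 met a region of the other replicate. Under 2 kb the shares were 55.7% (51.5 to 59.8) of 544 regions and 44.4% (40.2 to 48.7) of 520, which still lay above the 95% range of shifts, 9.56% to 18.2% and 9.23% to 17.7%. The longest regions of replicate 1 alone were 3.58 kb on 2R (13394533 to 13398116), 3.35 kb on X (3904892 to 3908244), 3.09 kb on 3L (14267730 to 14270819), 2.99 kb on 3L (15284134 to 15287118) and 2.98 kb on X (1497497 to 1500477), with scores from 0.413 to 0.756. In replicate 2 alone they were 4.73 kb on 3L (20541807 to 20546533), 4.45 kb on 2R (2281338 to 2285791), 4.44 kb on 3L (8812093 to 8816532), 4.35 kb on 3R (15184623 to 15188967) and 4.08 kb on X (2407516 to 2411591). Their scores were 0.552, 1.79, 0.455, 0.559 and 0.619. The 2R region lies in the stretch near 2.3 Mb with the high-scoring narrow regions.

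**Figure D4:**
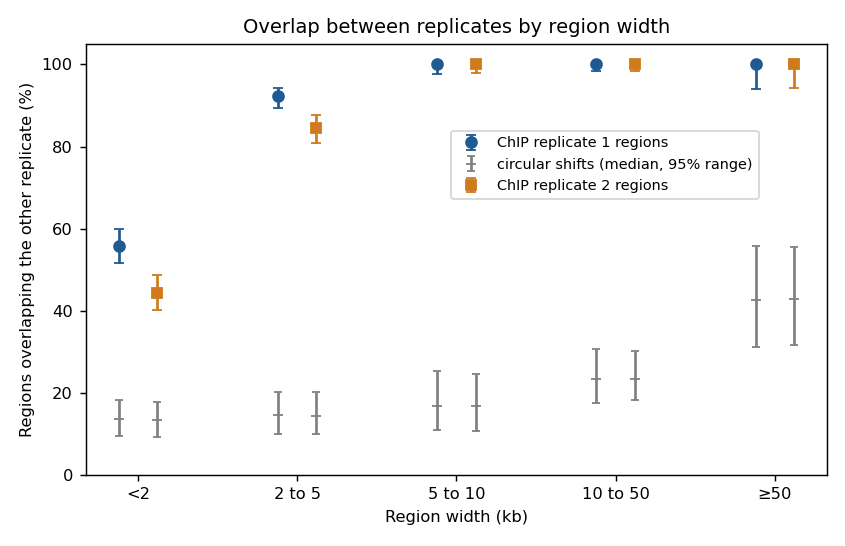
Percent of regions that overlap the other replicate by at least 1 bp, by region width in kb; circles are replicate 1, squares are replicate 2 and bars are 95% Wilson intervals. Grey marks are the median and 95% range of 1000 circular shifts, and all regions from 5 kb upwards lie at 100%.

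Where regions matched one to one, their ends were placed closely. Among 190 pairs of regions that matched one to one and were at least 10 kb wide in both replicates, the 380 ends differed by a median of 94.5 bp, 72.4% of them by at most 200 bp and 93.2% by at most 1000 bp. For all 719 one-to-one pairs the median difference was 191 bp. Scores of these 719 pairs correlated across regions with a Spearman coefficient of 0.91 (bootstrap interval 0.89 to 0.93) and a Pearson r of 0.98. The Spearman coefficient was 0.99 among the 190 broad pairs and 0.45 (0.27 to 0.59) among 119 pairs under 2 kb in both replicates. Pearson r was 0.99 for the broad pairs and 0.93 for the narrow ones, whose ranks by score agreed much less well. Widths had a Spearman correlation of 0.997 among the broad pairs and 0.083 among the narrow ones, which span only 1301 bp to 2 kb. Domains were not always cut in the same way. Of the broad regions, 39 of 300 in replicate 1 (13.0%) met 2 or more regions of replicate 2, and 99 of 311 in replicate 2 (31.8%) met 2 or more of replicate 1.

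The last comparison set the series list against the replicates, from which it is not independent. All 332 broad regions of the series list overlapped both replicates. In total, 844 of its 2279 regions (37.0%) overlapped both replicates and held 86.2% of its bases, while 226 overlapped replicate 1 alone, 282 replicate 2 alone and 927 (40.7%) neither. The 927 held 7.39% of its bases, with a median width of 1271 bp and a median score of 0.355, against 7146 bp and 0.617 for regions that overlapped both. Regions that overlapped replicate 1 alone or replicate 2 alone had nearly the same median scores as the 927, 0.358 and 0.359, at median widths of 1889 bp and 1983.5 bp. The narrowest region of the series list was 1001 bp, below the 1301 bp of the replicate lists, and 488 of the 927 were narrower than any replicate region. The highest score among the 927 was that of a 2571 bp region at the end of 3R (27902483 to 27905053, score 3.50). It was followed by shorter regions such as 1007 bp on 3R at 1849130 to 1850136 (score 3.20) and 1057 bp on 3L at 2447492 to 2448548 (score 2.91). These examples were chosen after the scores were seen.

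Base by base, 76.4% of the series list was called in both replicates, 80.8% in replicate 1 and 83.6% in replicate 2, and 12.03% in neither. Conversely, 99.7% of the bases of each replicate lay in the series list, and only 12 regions of replicate 1 and 7 of replicate 2 lay wholly outside it. Replicate 1 alone or replicate 2 alone left 1209 or 1153 regions of the series list without a match.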

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

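The 5 kb minimum, the shorter shifts, the major arms for counts of regions and the replicate width minimum were chosen only after the data were seen. Overlap between the replicates kept a permutation p of 1e-04 under each alternative run, with 59.1% to 94.4% of replicate 1 regions, 60.2% to 85.1% of replicate 2 regions and 86.4% to 89.4% of bases shared. The low ends of the region shares come from a 50% reciprocal overlap and their high ends from the 5 kb minimum. The 1 kb minimum removed no region and so tested nothing. With 50% reciprocal overlap the Spearman correlation of scores was 0.93. Called shares per arm fell with fewer regions, those at or above the median score, to 12.4% of 2L, 8.55% of 2R, 11.5% of 3L, 11.5% of 3R, 9.69% of X and 15.8% of 4, with chromosome 4 highest and 2R lowest as before. The share of series-list bases called in both replicates was 86.0% at or above its median score and 79.0% for regions at least as wide as the narrowest replicate region. Asking for 1 replicate only, it ranged from 80.8% to 83.6%. The number called in neither fell from 927 to 259 at or above the median score and to 439 at the replicate width minimum, where fewer regions are counted. No replicate could be left out of the overlap between replicates. No paired analysis was possible because the inputs that share the replicate numbers were not analysed here as lists of their own. Planned results on genes were not run, since no annotation of the files' build was used. Depth is unknown, so what it limits was not measured.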

Other observations

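The patterns in this part were noticed in the data, and the tests of scores as ratios, of short breaks, of the position of high-scoring series-list regions, of the width limit of the series list, of shifts of 100 kb to 1 Mb and of other limits for broad and near were chosen only after the result was seen. H3K27me3 domains were interrupted by short breaks, some of which recurred between replicates. Replicate 1 had 91 breaks under 2 kb between neighbouring regions of at least 5 kb each, and replicate 2 had 95, with median lengths of 621 bp and 590 bp. Of these, 38 overlapped a break of the other replicate by at least 1 bp, 41.8% (Wilson interval 32.2 to 52.0) and 40.0% (30.7 to 50.1). Of the others, 39 of replicate 1 and 21 of replicate 2 lay wholly inside a called region of the other replicate. Random placement of the breaks within their 2 flanking regions gave a median of 4 and a 95% range of 1 to 8 (one-sided permutation p = 5e-04, the smallest that 2000 draws can give). Examples chosen after they were seen are 2L from 11316156 to 11316993, 3L from 12565078 to 12565572 and 3R from 12624190 to 12624864 in replicate 1, each at the edge of one of the 4 longest stretches and overlapping a break in replicate 2 and in the series list. Mappability and GC content of the breaks were not examined.

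Neighbouring regions were also joined into chains, without a comparison to random placement. Joining regions less than 20 kb apart left 474 chains in replicate 1 and 462 in replicate 2, of which 204 and 201 were single regions. The chain with the most regions in replicate 1, 25, lay on 3L from 15157518 to 15349186. A chain on 3R from about 6.2 to 6.5 Mb (6245001 to 6500794 in replicate 1) held 22 regions over 256 kb in replicate 1 and 25 regions in replicate 2. Another on 3L near 6.3 Mb held 21 regions in each replicate and none wider than 11.3 kb. On 2R near 2.3 Mb (2224849 to 2306580 in replicate 1 and 2224787 to 2307509 in replicate 2), 10 regions of each replicate had median scores of 1.79 and 2.02, at median widths of 2177 bp and 2032 bp. Further along the arm, 18 regions of each replicate, from 2388896 to 2485017 in replicate 1 and from 2388937 to 2495940 in replicate 2, had median scores of 0.5355 and 0.508. Both stretches were picked out after they were seen.

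The first pattern is that narrow regions lay near broad ones: on the major arms, 145 of 536 narrow regions of replicate 1 (27.1%) and 160 of 511 of replicate 2 (31.3%) lay within 20 kb of a region of at least 10 kb, against a median of 7.85% and 8.21% under 2000 circular shifts (one-sided permutation p = 5e-04, the smallest possible). Shifts of 100 kb to 1 Mb gave medians of 8.28% and 8.78% and left a one-sided permutation p = 5.0e-04 in both replicates. That argues only against density that changes slowly, over more than 1 Mb. In places the called share changed more sharply, as from 0.135% to 39.1% between neighbouring 1 Mb windows of X. Such shifts do not keep density at that scale, so finer regional density stays open as a cause. The permutation p was also 5e-04 with a broad limit of 20 kb or a distance of 50 kb. Pieces split off a domain by the caller may account for part, since 34.5% and 23.75% of the near narrow regions lay inside a broad region of the other replicate or the series list. That share lies between the bounds set beforehand, so fragments and separate weak sites cannot be told apart for the rest, and no biological explanation was tested.

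The second pattern is the narrow regions that scored at or above the median of the broad ones, 5 in replicate 1, 4 in replicate 2 and 22 in the series list, of which 5, 3 and 3 lay in the single 2R stretch near 2.3 Mb. Their scores could be ratios of small whole counts, if the deposited score is a log2 ratio, which is not stated. Each score was compared with the list's most frequent score. In 5 of 5, 4 of 4 and 19 of 22 (86.36%) the difference was log2 of a ratio of whole numbers up to 50, within 1e-09. This held for 16.5%, 10.1% and 7.85% of the other narrow regions (Fisher's exact p = 1.4e-04, 1.2e-04 and 7.2e-18). Outside the 2R stretch only the series list held enough regions to tell (17 of 19, against 90 of 1146, Fisher's exact p = 1.0e-16). Since no read counts were used and numbers up to 50 were allowed, how few the reads were is not known. In a wider set, the 7 and 8 replicate regions under 3 kb at or above their list's 90th score percentile, 1 and 2 lay within 1 Mb of an arm end or on a scaffold, 5 and 5 lay in the 2R stretch, and 5 and 7 were called in the other replicate. The member on 2R that ended at 3904128 in replicate 1 and at 3904108 in replicate 2 lay just before a higher-scoring broad region. Whether members of this set were pieces split off a domain was not tested. Signal of a single library cannot hold for those called in both replicates, and stays open for the 2 and 1 that were not. Of the wider set, 71.4% in replicate 1 and 87.5% in replicate 2 were called in the other replicate. Among the other regions under 3 kb the shares were 66.6% and 55.0%, so the smaller difference was 4.844 percentage points. The sets are small, and neither difference reached p under 0.05 in Fisher's exact test (p = 0.0816 in replicate 2, the smaller p). For repeats only position was used. Members in the 2R stretch counted as away from arm ends, and repeats there were not examined. Repeats at arm ends or on scaffolds stay open for the wider set (odds ratio 2.351, interval 0.0503 to 19.9, and 3.58, 0.347 to 20.6), as most members share one stretch. In the series list such sequence is a candidate explanation beside small read counts, which were not measured. There 10 of the 22 lay within 1 Mb of an arm end or off the major arms (8 of them off the arms). The same was true of 90 of 1146 other narrow regions (odds ratio 9.736, interval 3.66 to 25.4, Fisher's exact p = 3.7e-06). Of the 22, 20 were called in neither replicate, against 72.9% of the others. Neither repeats themselves nor a biological explanation were tested.

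The third pattern is the 927 regions of the series list found in neither replicate. Of them, 47.36% were at least as wide as the narrowest replicate region. A smaller minimum width in that list accounts for these only if their sites were narrower in the replicates, which was not measured. One-to-one pairs under 2 kb in both replicates differed by a median of 217 bp per end, so widths alone cannot exclude it. For the other 52.64%, a lower width limit and a weaker signal cannot be told apart from widths alone. Background calls spread at random would lie near broad regions no more often than shifted ones, but 228 of 909 on the major arms (25.08%) lay within 20 kb of a broad region, against a 95% range of 6.47% to 11.9% under shifts. Among regions of the series list called in 1 replicate only the share was 30.3%. The excess among regions called in neither argues against background spread at random along an arm as the source of all of them. It cannot tell for those that lay farther from a broad region. The shifts do not keep finer regional density, so background calls that follow such density stay open. More reads behind the series list may also have lifted weak sites over the threshold, which was not tested, and no biological explanation was tested.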
